A study of Sus scrofa domesticus with 4 samples.

How the data were processed

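Gene expression was measured in slices of porcine endometrium cultured with or without orexin A (OXA) on 4 Agilent 2-colour oligonucleotide arrays. On each array 1 RNA from OXA-treated tissue and 1 RNA from untreated tissue were hybridised together, labelled with the dyes Cy3 and Cy5. Arrays are numbered 1 to 4 by the number in their titles, so array 1 is replicate 1. Per the labels, the tissue came from 4 gilts and cultures were run in duplicate in 4 separate experiments. Whether both RNAs of an array came from the same gilt is not given in the sources used here. In the main fit, which holds a dye coefficient, p-values of probes measure the spread between arrays with OXA in the same dye. That spread holds whatever mixture of animal, tissue piece and handling was present. The main p-values of gene lists measure a spread over genes, not over arrays. The labels give an OXA dose of 10 nM, and the design text of the series gives 10 µM.

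The deposited scanner files hold the median pixel intensity of each spot and of its local background in both dyes, as written by Agilent Feature Extraction 10.7.3.1 per the file headers. They also hold processed intensity values and a log10 ratio of Cy5 over Cy3, which the authors' software had background-subtracted, detrended and dye-normalized per the file headers. The deposited value table of the series holds log2 ratios. Its columns were set against the scanner ratios over 43420 shared probes, with slopes of 1.06, -1.00, 1.04 and -1.03 on arrays 1 to 4, which gave a log2 scale and a direction of OXA over control under the dyes named for each sample. The column medians were -0.17, 0.06, -0.06 and 0.09, and how those columns were centred stays unknown.

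The dye that carried each RNA was described in 2 ways. The dye labels of the single samples, the short descriptions of their ratios and the value table put OXA in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The labelling protocol, worded alike for every sample, puts OXA in Cy5 throughout. The labels of the single samples were used, and the other reading was run as an alternative chosen after the data were seen.

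Signals were computed from the median intensities, since the files hold medians and not means. Background was corrected with normexp (offset 50), each array was normalized by loess, and Cy5 over Cy3 log2 ratios were fitted in limma 3.58.1 under R 4.3.3 with an OXA coefficient (positive where OXA was in Cy5, negative where it was in Cy3) and a dye coefficient. Moderated tests by eBayes were adjusted by Benjamini-Hochberg over all probes kept. With 4 arrays and 2 coefficients the fit had 2 residual degrees of freedom and 3.88 after moderation. Control spots and outlier-marked spots were left out, replicate spots of a probe were averaged, and a probe was kept when it was well above background in at least 4 of its 8 readings. Of 43603 probes, 26927 were tested, and 135 were lost to outlier spots. Normexp with this offset pulls the ratios of dim probes toward 0. How much of that came from the offset and how much from the normexp fit was not tested. PDK1, a dim gene, was -0.31 with it, -0.79 with no background correction and -1.08 in Agilent's log ratio. In Cy3 the negative-control spots lay well above the local background (medians of 154 to 251 against 24 to 59.5). In Cy5 they lay above it by less (68 to 74 against 32 to 40). What this did to the ratios was not tested.

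Gene names came from the RefSeq accessions in the scanner files, matched without versions to the reference gene table of assembly Sscrofa11.1. Of 7125 probes with such an accession, 6700 matched, naming 3029 genes. The other 36903 probes stayed unnamed here, among them 8889 with Ensembl transcript identifiers. Genes were represented by their kept probe of highest mean brightness, which left 2407 named genes. The file headers name no genome build for the array, so no coordinates are given.

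Choices made before the data were examined were the design, the gene lists and the naming rule. The rule was to name the 12 genes with the largest change in each direction among those past an adjusted p of 0.05 with the same sign on 4 of 4 arrays, and to fill free places by lowest unadjusted p among genes of the same sign on 4 of 4 arrays with a fold of at least 1.2. It also named up to 4 members of each list by lowest unadjusted p, and the genes for the orexin precursor and both orexin receptors. A looser count used an unadjusted p under 0.05 with a fold of at least 1.2. There were 28 lists, 17 of biological processes and 11 of cell type markers, holding 775 genes, of which 37 have no symbol in the reference table. The 24 lists with at least 3 measured genes were tested two-sided with limma's camera (correlation preset to 0.01), with Benjamini-Hochberg adjustment over the lists. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way.

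The scripts were tested on simulated data. Among 26927 simulated probes with the real spread, 50 were changed at each of 4 sizes, and the test called 2% of them at a fold of 1.5, 40% at 2, 64% at 3 and 76% at 4, with 2 false calls. In the list test over 2407 simulated genes, a list of 14 genes shifted by -0.5 was called and none of the other lists was. Probes and genes were simulated as independent. In the real lists the estimated correlation was 0.33 for glycolysis and hypoxia and 0.82 for epithelium. The simulation therefore does not show how often lists of correlated genes are called falsely. In limma's test 5.88% of unchanged simulated probes had an unadjusted p under 0.05, against 500 of 26927 probes on the real arrays. The planted shift of -0.5 was also larger than the median of the called glycolysis and hypoxia list, -0.25. The shares called may thus not carry over to the real arrays.

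Alternatives covered the dye coefficient, no background correction, Agilent's log ratio, the value table, median centring, Aquantile between arrays, 2 other filters on dim probes, an intensity trend with robust fitting, a one-sample t-test, array weights, each array left out, the estimated correlation, fry and the mean over a gene's probes. Array 1 was on another slide and was scanned 71 days after the others. As it was the only array of its slide, a slide block gave it a coefficient of its own, which equals leaving it out, and those values are given as within-slide values. With an array left out, 1 dye orientation holds a single array, which weighs as much in the OXA coefficient as the other pair together and is assumed to vary like the others, while the residual spread, with 1 degree of freedom before moderation, comes from the remaining pair. Of the 24 named genes, 1 is not reported here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.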

Results

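The series asked how orexin A (OXA), a neuropeptide hormone known for its part in feeding and arousal, alters gene expression in the lining of the uterus in early pregnancy. Endometrial slices from 4 gilts (Large White x Polish Landrace) on days 15 to 16 of gestation were kept in culture for 2 h and then for 24 h with OXA at 10 nM or without it; the design text of the series gives 10 µM. Each of 4 arrays set 1 OXA-treated RNA against 1 untreated control RNA, and values below are log2 ratios of OXA over control with n = 4 arrays unless stated. OXA was in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4 by the labels of the single samples, while the labelling protocol puts it in Cy5 on every array. The share of probes well above background was 62.3% to 74.5% in Cy5. In Cy3 it was 52.1% to 56.7% on arrays 2 to 4 and 31.7% on array 1, which was on another slide and was scanned 71 days after the others. No spot was saturated, and the number of arrays limits the precision.

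Among the 12 named genes higher with OXA, MMP1 (interstitial collagenase, a protease of fibrillar collagen) had the largest value, 0.96 ± 0.20 (SD, n = 4), a fold of 1.94. It was above control on 4 of 4 arrays, as the naming rule requires, with 0.78 as the lowest value. MMP3 (stromelysin, another matrix protease) was 0.46 (SE 0.17), with 1.10 on array 3 and 0.20 to 0.29 on the rest, and 0.24 without array 3. HSPD1, the mitochondrial chaperonin, was 0.69 (SE 0.22), with 0.01 on array 4, and without array 2 it was 0.40. Its 12 probes all pointed the same way, from 0.27 to 0.75. ALG2 (a mannosyltransferase of N-glycan assembly) was 0.62 (SE 0.22), but its other probe gave -0.22, and without array 1 it was 0.39. C1S, a serine protease of the complement cascade, was 0.61 (SE 0.10), with 0.09 on array 2. NOP56, a nucleolar protein of ribosomal RNA modification, was 0.43 (SE 0.06), and ATP5O, a subunit of mitochondrial ATP synthase, was 0.37 (SE 0.07), with 9 of 10 probes in that direction. The other 5 were SULT2A1 (a steroid sulfotransferase), TPBG (trophoblast glycoprotein), AXL (a receptor tyrosine kinase), PHYH (a peroxisomal hydroxylase) and STEAP1 (a membrane protein), from 0.27 to 0.39. Without array 2 SULT2A1 was 0.23, and without array 1 TPBG was 0.23. The other probe of SULT2A1 gave 0.07, and 3 of 4 AXL probes pointed up, with the lowest at -0.04. With no background correction and with Agilent's log ratio, MMP3 was 0.74 and 0.78, and STEAP1 0.49 and 0.47.

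Among named genes lower with OXA, DDIT4 (a stress-induced inhibitor of mTOR signalling) was -1.13 (SE 0.26), with -2.50 on array 3 and -0.15 on array 2. Its 4 probes ran from -1.15 to -0.30. NMB, the precursor of the peptide neuromedin B, was -1.01 (SE 0.14), a fold of 0.498. MT1A, a metal-binding metallothionein, was -0.81 ± 0.13 (SD, n = 4), and its other probe gave -0.82. IL6, the inflammatory cytokine, was -0.65 (SE 0.14), and its other probe gave -0.26. PTMA (prothymosin alpha) was -0.54 (SE 0.13), with -0.01 on array 3, and its other probe gave -0.27. TCTEX1D4 (a dynein light chain protein) was -0.49 (SE 0.08). BTG1, an antiproliferative factor, was -0.45 ± 0.03 (SD, n = 4), with 4 of 4 probes below 0 (-0.45 to -0.25). P4HA1 (a collagen prolyl hydroxylase induced by hypoxia) was -0.42 (SE 0.08), with 7 of 7 probes below 0 (-0.43 to -0.12) and -0.02 on array 4. PDK1 (pyruvate dehydrogenase kinase), GNAS (the stimulatory G protein alpha subunit) and APOA1 (apolipoprotein of high-density lipoprotein) were -0.31, -0.27 and -0.27. The other probe of PDK1 gave -0.05, and the 14 probes of GNAS ran from -0.27 to -0.05. With no background correction and with Agilent's log ratio, PDK1 was -0.79 and -1.08, P4HA1 -0.68 and -0.79, and APOA1 -0.43 and -0.50. With median centring in place of loess GNAS was 0.08 and P4HA1 0.02, below the median of all probes under that scaling, 0.14, and the sign of every other named gene held under each scaling. The sizes did not hold with median centring: BTG1 was -0.11, TCTEX1D4 -0.06, IL6 -0.23, PTMA -0.19, PDK1 -0.06, APOA1 -0.05, MT1A -0.46 and NMB -0.53, while the higher genes moved up, such as PHYH to 0.73 and MMP1 to 1.34.

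None of these genes passed limma's test over all 26927 probes (adjusted p = 0.763 for each), and no probe did. At an unadjusted p under 0.05 there were 500 probes, where chance alone gives 1346, and 349 of them had a fold of at least 1.2, 168 higher and 181 lower. An intensity trend with robust fitting called 3 probes, BTG1 (adjusted p = 0.0274), MMP1 (adjusted p = 0.0470) and 1 unnamed probe at -0.49. On simulated data with this spread and independent probes, 40% of probes changed by a fold of 2 were called. There 5.88% of unchanged probes had an unadjusted p under 0.05 in the same test, unlike on the real arrays, so that share may not carry over. Without array 3 the looser count was 3120, without array 4 it was 2060, and within the slide of arrays 2 to 4 it was 285.

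**Figure D1:**
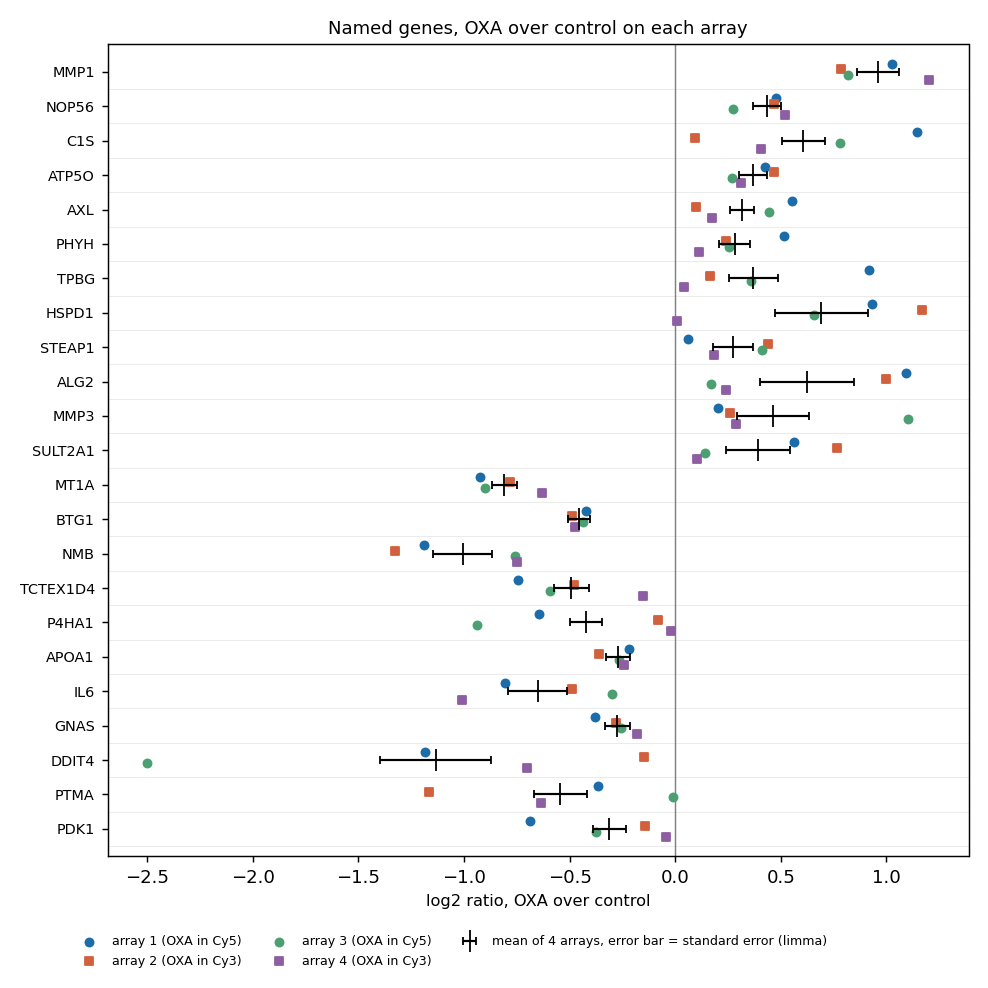
Log2 ratio of OXA over control (horizontal axis) of the named genes (vertical axis), with a point per array coloured by array, circles for OXA in Cy5 and squares for OXA in Cy3, and a black bar for the mean of 4 arrays with its standard error from limma. MMP1 lay at 0.78 or above on every array and BTG1 between -0.49 and -0.42, while DDIT4 reached -2.50 on array 3.

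Glycolysis and hypoxia genes, which break down glucose or respond to low oxygen, fell with OXA as a list. Of 14 measured genes 13 were below 0, with a median of -0.25, against 0.03 with median centring in place of loess, where the median of all probes was 0.14. The shift passed camera's test (adjusted p = 8.4e-05; adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone 2 genes passed against 0 over all genes, PDK4 (pyruvate dehydrogenase kinase) at -0.76 (SE 0.11; adjusted p = 0.0302) and P4HA1 (adjusted p = 0.0381). PDK4 was -1.40 and -1.56 where OXA was in Cy5 but -0.28 and 0.20 where it was in Cy3, and P4HA1 was -0.65 and -0.94 against -0.08 and -0.02. The dye coefficient takes up such a split (-0.72 for PDK4), so a small SE, here or elsewhere, does not show that the arrays agreed. HK1 (hexokinase) was -0.35 (SE 0.11). The array medians were -0.12, -0.18, -0.75 and 0.01, and without array 3 the median was -0.18 and the call was lost (adjusted p = 0.506). Within the slide of arrays 2 to 4 the median was -0.43, but there array 3 alone had OXA in Cy5 and weighed as much as arrays 2 and 4 together, with the spread taken from arrays 2 and 4 only. With Agilent's log ratio and the authors' table the median was -0.43 as well and called. The list was also called lower on the dye coefficient (-0.16; adjusted p = 1.8e-04).

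Immediate early and MAPK response genes, transcription factors switched on soon after a stimulus, also fell as a list. Of 11 measured genes 10 were below 0, with a median of -0.20, against 0.02 with median centring, below that of all probes. The shift passed the test (adjusted p = 0.00280; adjusted p = 0.635 with an estimated correlation), but not with no dye coefficient (adjusted p = 0.0664). With Agilent's log ratio and the authors' table the median was -0.31 and called. On the dye coefficient the list was called lower at about the same size (-0.19; adjusted p = 0.00317). JUN was -0.50 (SE 0.17), BTG2 -0.40 (SE 0.11), KLF2 -0.30 (SE 0.11) and KLF10 -0.20 (SE 0.08), and 0 genes passed over all genes or adjusted over the list alone. The median was -0.53 on array 1 and -0.07 to 0.03 on the others; on array 1 the epithelium list stood at -0.64 and the stromal list at 1.44. Without array 3 the call was lost (adjusted p = 0.110), though the median was -0.29, and within the slide of arrays 2 to 4, where array 3 alone had OXA in Cy5, it was -0.19.

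**Figure D2:**
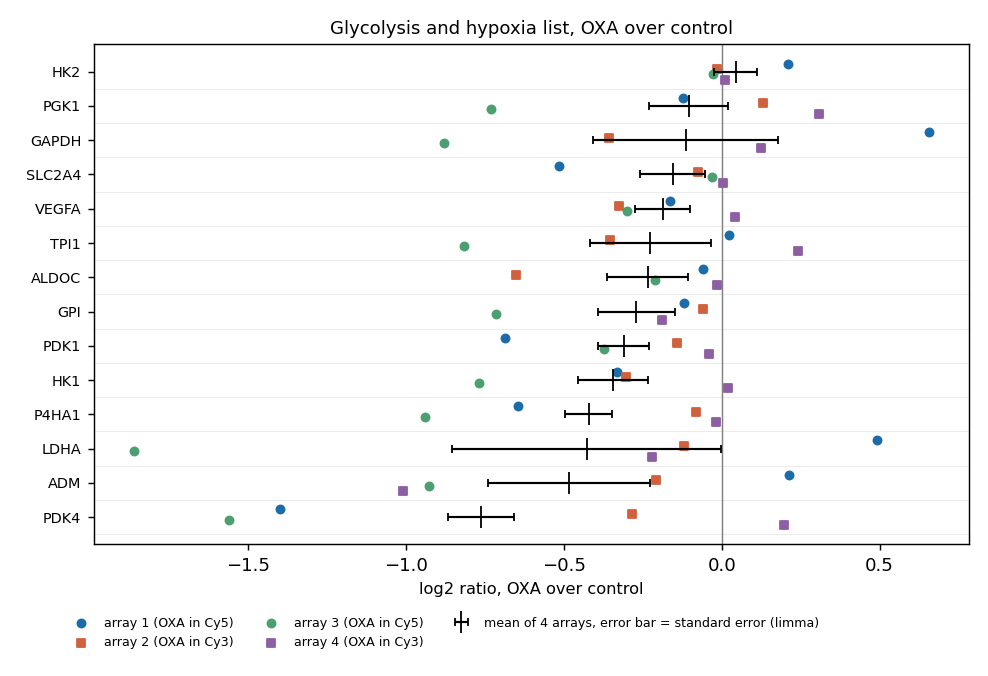
Log2 ratio of OXA over control (horizontal axis) of the 14 measured glycolysis and hypoxia genes (vertical axis), with a point per array coloured by array, circles for OXA in Cy5 and squares for OXA in Cy3, and a black bar for the mean of 4 arrays with its standard error. On array 3 all 14 genes lay below 0, against 9 on array 1, 13 on array 2 and 6 on array 4; with median centring in place of loess the list's median was 0.03, below the median of all probes, 0.14.

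Antigen presentation genes of the swine leukocyte antigen (SLA) complex and the cytokines and chemokines also fell as lists under the dyes of the labels. The SLA list had 12 of 14 genes below 0 and a median of -0.23 (adjusted p = 0.00148), against 0.02 with median centring, below that of all probes. It was not called with an estimated correlation (adjusted p = 0.635), with no dye coefficient (adjusted p = 0.137), with Agilent's log ratio (-0.29; adjusted p = 0.0735) or with the authors' table (-0.29; adjusted p = 0.0790). Its members included SLA-DRA at -0.46 (SE 0.14), SLA-DQA1 at -0.38 (SE 0.11), SLA-3 at -0.33 (SE 0.08) and SLA-DQB1 at -0.31 (SE 0.07). The cytokine list had 29 of 37 genes below 0 and a median of -0.12 (adjusted p = 0.00201), against 0.01 with median centring, below that of all probes. It was not called with an estimated correlation (adjusted p = 0.635), while its median was -0.26 with no background correction and -0.34 with Agilent's log ratio and the authors' table, and called in each. Its members included CXCR4 (a chemokine receptor) at -0.41 (SE 0.12) and CXCL2 (a neutrophil attractant) at -0.35 (SE 0.11). The estimated correlations of the SLA and cytokine lists were 0.016 and 0.014, near the preset 0.01. Losing the call with an estimated correlation therefore does not show correlated genes in them. In camera the unadjusted p of the SLA list went from 1.2e-04 to 0.065 at nearly the same correlation. The estimates are made after the OXA and dye coefficients are taken out, so a joint split by dye is not in them. Low estimates thus do not show that the genes of these lists move independently. In both lists 0 genes passed over all genes or adjusted over the list alone. Their arrays split by dye. The SLA medians were 0.11 and 0.21 on arrays 1 and 3 but -0.66 and -0.59 on arrays 2 and 4, and the macrophage and other myeloid markers followed the same split (0.36 and 0.12 against -0.40 and -0.44). With OXA read as Cy5 on all arrays, the SLA median was 0.42 (adjusted p = 4.5e-05) and the cytokine median 0.12 (adjusted p = 4.4e-04), so the direction turned. Without array 3 both calls were lost (adjusted p = 0.110 for each), though the medians were -0.29 and -0.17. Within the slide of arrays 2 to 4 the medians were -0.14 and -0.10, but array 3, the only array there with OXA in Cy5, had means above 0 (0.26 and 0.18).

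Oxidative phosphorylation genes, which encode the respiratory chain, rose as a list by a small amount. The median was 0.06 with 13 of 15 genes above 0 (adjusted p = 0.0422; adjusted p = 0.635 with an estimated correlation), against 0.40 with median centring (adjusted p = 0.0264), where the median of all probes was 0.14. It was not called with Agilent's log ratio (0.09; adjusted p = 0.0789), with the authors' table (0.06; adjusted p = 0.0975) or among probes well above background in all 8 readings (0.06; adjusted p = 0.0986). In this list 0 genes passed over all genes or adjusted over the list alone. ATP5O was 0.37, NDUFA4 0.19 (SE 0.14) and PPARGC1A, a regulator of mitochondrial genes, 0.16 (SE 0.08), while COX7C was -0.20 (SE 0.09). Without array 3 the median was 0.07 but the call was lost (adjusted p = 0.302), and without array 4 the median was 0.00 (adjusted p = 0.423). Without array 2 it was 0.13 (adjusted p = 0.00153). Within the slide of arrays 2 to 4, with array 3 alone having OXA in Cy5, the median was 0.07. With OXA read as Cy5 on all arrays the median was 0.04 and the test pointed down (adjusted p = 0.961).

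With median centring in place of loess, the median of all probes moved from 0.02 to 0.14. Under that scaling the tests of the 4 lower lists still pointed down, but of these 4 only the cytokine list was called (adjusted p = 0.0264). Oxidative phosphorylation stayed called, and extracellular matrix (0.34) and stromal fibroblast genes (0.72; adjusted p = 0.0318 for each) were called higher too.

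**Figure D3:**
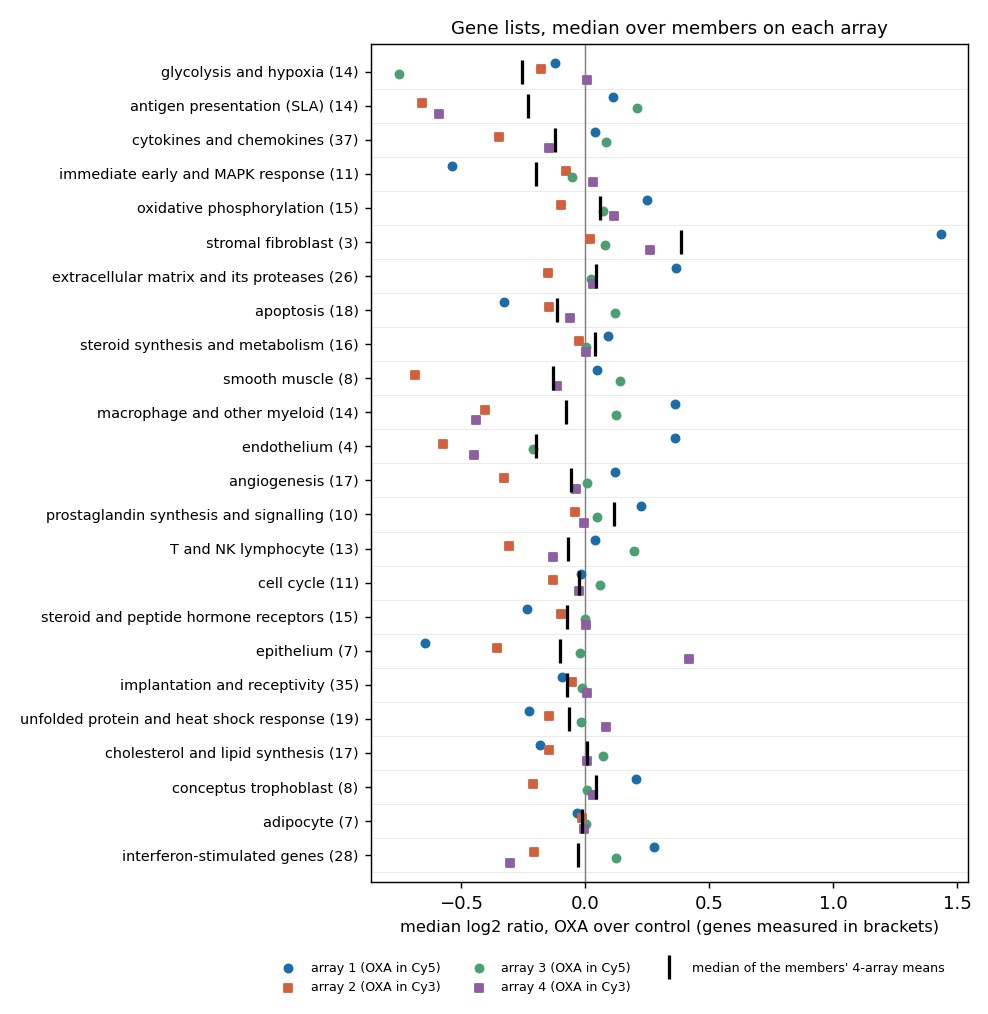
Median log2 ratio of OXA over control (horizontal axis) of the 24 tested gene lists (vertical axis, number of measured genes in brackets), with a point per array coloured by array, circles for OXA in Cy5 and squares for OXA in Cy3, and a black bar for the median of the members' means over 4 arrays. The stromal fibroblast list stood at 1.44 on array 1 and at 0.02 to 0.26 on the others, and the SLA list at 0.11 and 0.21 where OXA was in Cy5 and at -0.66 and -0.59 where it was in Cy3.

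The extracellular matrix and its proteases had 17 of 26 genes above 0 and a median of 0.05 (adjusted p = 0.0949), and the list was called higher in 4 of 18 alternatives, among them without array 2 (0.12; adjusted p = 0.00502) and without array 3 (0.18; adjusted p = 0.0354). Adjusted over the list alone MMP1 passed (adjusted p = 0.0192), against 0 genes over all genes, and LOX (a collagen cross-linking oxidase) was 0.31 (SE 0.16). On array 1, where the stromal fibroblast markers stood at 1.44, the matrix list was at 0.37, and on the other arrays it was -0.15 to 0.03. In the remaining lists of biological processes no shift passed, and 0 genes passed over all genes or adjusted over the list alone. Medians were 0.12 for prostaglandin synthesis and signalling (adjusted p = 0.238), with PTGES (a prostaglandin E synthase) at 0.15 (SE 0.07), and 0.04 for steroid synthesis and metabolism (adjusted p = 0.180), with HSD17B7 at 0.22 (SE 0.06). Apoptosis genes had a median of -0.11 (adjusted p = 0.180; -0.09 and adjusted p = 0.0429 without array 2), with GADD45A at -0.50 (SE 0.19), and angiogenesis genes -0.06 (adjusted p = 0.215), with ANGPT2 at -0.34 (SE 0.13). GADD45A ran from -1.39 on array 1 to 0.05 on array 4. Implantation and receptivity genes had a median of -0.07 (adjusted p = 0.636), with the integrin subunit ITGB3 at 0.56 (SE 0.24), from -0.77 on array 4 to 1.98 on array 1, and STC1 at -0.25 (SE 0.10). Steroid and peptide hormone receptors had a median of -0.07 (adjusted p = 0.432), with the oxytocin receptor OXTR at 0.17 (SE 0.09). The unfolded protein and heat shock response had -0.06 (adjusted p = 0.823), its members going both ways, with ATF4 at -0.41 (SE 0.07) and DNAJB1 at -0.48 (SE 0.13) beside HSPD1 at 0.69. Cell cycle genes had -0.02 (adjusted p = 0.426) and interferon-stimulated genes -0.03 (adjusted p = 0.975), with ISG15 at -0.52 (SE 0.24) and B2M at -0.33 (SE 0.06), which was 0.34 and 0.14 with OXA in Cy5 but -0.92 and -0.88 with OXA in Cy3. For cholesterol and lipid synthesis the median was 0.01, the mean -0.03 and the test pointed up (adjusted p = 0.823), with FASN at 0.41 (SE 0.18) and SREBF1 at -0.45 (SE 0.24). SREBF1 ran from -1.25 on array 1 to 0.07 on array 4.

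Among cell type markers, the 3 measured stromal fibroblast genes LUM, DCN and COL1A2 were 0.39, 0.43 and 0.31, with a median of 0.39 that missed the threshold (adjusted p = 0.0506). The list was called higher in 7 of 18 alternatives, among them no background correction (0.43; adjusted p = 0.0151), array weights (adjusted p = 0.0267), without array 2 (0.51; adjusted p = 0.00108) and without array 3 (0.65; adjusted p = 0.0354). Without array 1 that median was -0.02 (adjusted p = 0.549). The 7 epithelium genes had a median of -0.10 (adjusted p = 0.535), from -0.64 on array 1 to 0.42 on array 4, with the tight junction genes CLDN3 at -0.45 (SE 0.31) and CLDN4 at -0.54 (SE 0.41). CLDN3 ran from -1.34 on array 1 to 0.75 on array 4, and CLDN4 from -1.86 on array 1 to 0.22 on array 4. Smooth muscle (-0.13; adjusted p = 0.180), endothelium (-0.20; adjusted p = 0.197), macrophage and other myeloid (-0.08; adjusted p = 0.188), and T and NK lymphocyte markers (-0.07; adjusted p = 0.403) did not pass. Macrophage and other myeloid markers were called lower in 5 of 18 alternatives: no background correction (-0.37; adjusted p = 0.00146), Agilent's log ratio (-0.41; adjusted p = 0.00393), the authors' table (-0.41; adjusted p = 0.00441), without array 2 (-0.13; adjusted p = 0.00120) and within the slide of arrays 2 to 4 (-0.15, with array 3 alone having OXA in Cy5). With OXA read as Cy5 on all arrays they were called higher (0.26; adjusted p = 1.8e-05). Endothelium was called lower within that slide (-0.35) in the same fit. Without array 4 smooth muscle (-0.27) and epithelium (-0.26) were called lower (adjusted p = 0.0141 for each). Conceptus trophoblast (0.04; adjusted p = 0.866) and adipocyte markers (-0.01; adjusted p = 0.870) did not either. The lists of B and plasma cells, ciliated epithelium and erythrocytes had 2, 1 and 0 measured genes and were not tested; SPAG6, the measured ciliated gene, was -0.34 (SE 0.17), and of the B cell genes CD79A was -0.12 (SE 0.09), with -0.42 on array 1 and -0.04 or nearer 0 on the others, while LOC396781 was 0.10.

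For the orexin system itself, HCRT, which encodes the precursor of the orexins, was 0.01 (SE 0.06; adjusted p = 0.923), and its probe was well above background in 7 of 8 readings. Its mean log2 brightness, 10.19, was near that of the dim genes CCNB2 (10.15) and CD79A (10.05). The background correction pulls such ratios toward 0, so this value does not show that HCRT was unchanged. The receptor genes HCRTR1 and HCRTR2 were well above background in at most 1 and 2 of 8 readings and were not tested.

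The 4 arrays shared little of a common response. Across probes, which are not independent replicates, the ratios turned to OXA over control correlated between pairs of arrays with Pearson's r from -0.29 (arrays 3 and 4) to 0.42 (arrays 1 and 2), with a mean of 0.03 ± 0.24 (SD over 6 pairs). Pairs of the same dye orientation had r = 0.11 (arrays 1 and 3) and r = 0.07 (arrays 2 and 4). The sign was the same on 4 of 4 arrays for 11.9% of probes, where chance gives 12.5%. No probe had a dye effect past the threshold in the same limma fit, with 1042 at an unadjusted p under 0.05, while 11 gene lists were called on the dye coefficient, 6 of them higher in Cy5.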

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

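The tests of explanations given here were chosen after the results were seen. Ratios of 4 arrays were compared for 114 named genes, 24 gene lists and 8 array measures, and in 10 of these 146 sets 1 array lay far from the other arrays, where chance gives about 1 in 20, or 7.3. Array 1 stood apart in 9 of the 10. Its ratios over all tested probes had the widest spread (SD 0.46, against 0.32, 0.18 and 0.17 on arrays 2 to 4). The 1 in 20 assumes arrays of equal spread, so it does not apply as stated. Among genes, array 1 had CCNB2 (cyclin B) at -1.02 against 0.00 to 0.04 on the others. PCK1 (a gluconeogenic enzyme) was -1.01 there against -0.04 to 0.06. CD79A (a B cell receptor component) was -0.42 against -0.04 to -0.00. FABP4 (a fatty acid carrier) was -0.26 against -0.03 to 0.01. STAR (which moves cholesterol into mitochondria) was 0.54 against -0.00 to 0.01. FABP4 and STAR were well above background in 4 of 8 readings and CD79A and CCNB2 in 6 of 8. These dim genes thus lie near the floor, where the background correction pulls ratios toward 0, and their places apart rest on little signal. PCK1 and MMP3 were well above background in 8 of 8. On array 3 MMP3 was 1.10 against 0.20 to 0.29. The negative-control spots of array 1 had a Cy3 median of 251 against 154 to 166, a Cy3 median absolute deviation of 72.6 against 6.67 to 8.15, and a Cy5 one of 9.64 against 5.93.

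The stromal fibroblast list, with LUM, DCN and COL1A2, stood at 1.44 on array 1 and at 0.02 to 0.26 on the others, while the epithelium list was at -0.64 on array 1. A loss of epithelium alone would raise the markers of every other cell type alike, but there the stromal mean exceeded the smooth muscle mean by 1.21 (SE 0.22). That SE takes 3 stromal and 8 smooth muscle genes of 1 array as independent, while their lists had estimated correlations of 0.89 and 0.51. It measures no spread between tissue pieces, so how firmly the gap speaks against that explanation is unknown. Whether the weak Cy3 channel made the ratios of array 1 unreliable stays open. In Agilent's log ratio, 10 spike-in probes on array 1 correlated with their means over arrays 2 to 4 at r = 0.988. A correlation over 10 control probes cannot speak for the probes of the tissue's own genes. Of the stromal probes 3 of 3 were well above background in both channels, so their values do not rest on signal at background. A higher share of stromal fibroblasts in the OXA-treated slice may account for the pattern and stays open, with matrix genes outside the list at a mean of 0.31 (SE 0.18) on array 1 and 20 of 26 above 0. A response to OXA in this tissue alone is also untested, and the slide and scan day, which array 1 shares with no other array, cannot be told apart from either.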

How the results depend on the processing

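The reading with OXA in Cy5 on all arrays was chosen after the data were seen; the other alternatives were planned. The cause of a difference was not tested unless it is given. No probe passed the adjusted test in any alternative except with an intensity trend and robust fitting (3 probes, BTG1, MMP1 and 1 unnamed) and without array 4 (6 unnamed probes, all lower), so the range over left-out arrays was 0 to 6. The looser count of 349 probes was 1406 with no background correction, 1829 with Agilent's log ratio, 1824 with the authors' value table, 4297 with median centring, 81 with a one-sample t-test, 193 with array weights, 679 with OXA in Cy5 on all arrays and 285 to 3120 without each array in turn, the highest without array 3 and 2060 without array 4. Of these calls 48.1% were higher with OXA, against 68.9% with Agilent's log ratio, 68.6% with the value table and 99.9% with median centring, which leaves the brightness-dependent dye trend in and moved the median of all probes to 0.14. Dye calls went from 0 to 8221 with median centring and ranged from 0 to 7 without each array. The mean correlation between arrays stayed within 1 SD of 0.03, from -0.19 to 0.17.

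The number of called lists was 5. It was 3 with no dye coefficient, 8 with no background correction, 11 with OXA in Cy5 on all arrays, 0 with an estimated correlation, 0 with fry, and 2 to 9 without each array, with 2 without array 3 (extracellular matrix at 0.18 and stromal fibroblast at 0.65) and 9 without array 2. Of 18 alternatives, glycolysis and hypoxia kept its call and direction in 14, cytokines in 14, immediate early genes in 13, and SLA and oxidative phosphorylation in 10 each. The 18 were not all separate checks, so these tallies overstate how firmly a call held. The trend with robust fitting cannot change a list test and repeated the main values, and Aquantile left these medians unchanged. The value table largely repeats Agilent's log ratio, with the same glycolysis median of -0.43. With OXA in Cy5 on all arrays, the direction of the test turned for 7 lists called under either reading: SLA (0.42), macrophage and other myeloid (0.26), smooth muscle (0.26), T and NK lymphocyte (0.17), cytokines (0.12), interferon-stimulated (0.12) and oxidative phosphorylation (median 0.0399, test down). It also turned for angiogenesis, cell cycle, cholesterol and lipid synthesis, and endothelium, called under neither. Of 24 lists 7 kept the direction of their test in every alternative, and of the 24 named genes 12 kept their sign. Of the other 12, the sign of GNAS and P4HA1 turned with median centring and that of 10 with OXA in Cy5 on all arrays, none as a call. The weak Cy3 channel of array 1, with 31.7% of probes well above background, limits what dim genes can show.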

Other observations

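The tests of explanations given here were chosen after the results were seen. The medians of 5 lists of immune genes were higher in Cy5 than in Cy3 on all 4 arrays, whichever RNA carried that dye. The median log2 ratio of Cy5 over Cy3 was 0.11, 0.66, 0.21 and 0.59 on arrays 1 to 4 for the SLA list, 0.36, 0.40, 0.12 and 0.44 for macrophage and other myeloid markers, and 0.28, 0.21, 0.13 and 0.30 for interferon-stimulated genes. The pattern was not limited to immune genes: smooth muscle markers were at 0.05, 0.68, 0.14 and 0.11 and were called on the dye coefficient as well (0.26; adjusted p = 0.0260), and angiogenesis and prostaglandin lists also lay above 0 on all 4 arrays without a call. In all, 18 probes were higher in Cy5 by at least 0.5 on all 4 arrays and 0 were lower by as much. Turned to OXA over control, 8 probes differed by at least 0.5 in 1 direction on all 4 arrays, 1 of them higher with OXA. Of the 18 probes higher in Cy5, 14 had names, in 9 genes chosen after their values were seen. They included the chemokine CXCL9 (dye coefficient 1.46), the acute phase protein SAA3 (1.25, 1.13 and 1.11 over 3 probes), the complement component C3 (0.95, 0.87 and 0.83 over 3 probes), the iron store FTH1 (1.04), UBD (0.81) and SLA-DRB1 (0.77 and 0.68).

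A shared response to OXA under the dyes of the labels would not put the same genes higher in Cy5 on every array. After turning to OXA over control, 5 of 5 immune lists had a mean above 0 on an array and below 0 on another. Each lay beyond 2 standard errors over members, such as 0.26 (SE 0.06) on array 3 and -0.57 (SE 0.10) on array 2 for the SLA list. Opposite signs after turning follow from the pattern itself, so they are no separate test. The standard errors take the genes of 1 array as independent. Dye bias that differs between the probes of a gene is argued against by the pairs of brightest probes. Their dye coefficients correlated across 53 immune genes at r = 0.888 (95% interval 0.813 to 0.934). A dye bias of whole transcripts, or probes that overlap in sequence, stays open. OXA in Cy5 on all arrays, as the labelling protocol says, might give the pattern, and the mean correlation between arrays as scanned exceeded that after turning by 0.0101 (SD over pairs 0.24), which leaves it open. If OXA was in Cy5 on all arrays, the SLA median with OXA would be 0.42, and MMP1 and BTG1 would be at -0.04 and 0.03.

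Glycolysis and hypoxia genes were lower with OXA, mostly on array 3. A dye bias of 1 sign on all 4 arrays is argued against as the whole cause by arrays 2 and 3, a pair chosen after the values were seen, on which 92.9% of the genes (13 of 14) had opposite signs of Cy5 over Cy3; the medians of Cy5 over Cy3 were -0.12, 0.18, -0.75 and -0.01 on arrays 1 to 4, and a dye bias that differs between arrays stays open. The same list was called on the dye coefficient, which holds no treatment under the dyes of the labels (adjusted p = 1.8e-04) but is the OXA effect if OXA was in Cy5 on all arrays (-0.16 in that fit; adjusted p = 0.00431), a result under the first reading in line with genes of 1 pathway moving together between slices whatever the treatment. A response to OXA on all 4 arrays is not excluded, but without array 3 the list had a median of -0.18 and an adjusted p = 0.506, and each fit with an array left out has a single array in 1 dye orientation. A hypothesis to test on more animals is that slices differ in oxygen supply or glucose use, which may move these genes by more than OXA does.

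The signs of 4 arrays can be set in 8 ways, counting mirrors as the same, and these splits were fitted with no dye coefficient. A looser count as large as the real 323 came from 5 of 8 splits, with 1054 as the highest other, and as many lists as the real 3 came from 7 of 8, with 11 as the highest other. For calls at an adjusted p under 0.05, 8 of 8 splits gave as many as the real 0, and the highest other was 0. With 8 splits no share under 0.05 can be reached. The split that sets the Cy5 ratio of array 1 against the others, as the slide does, gave 647 probes and 5 lists, and the split that leaves all ratios as scanned gave 679 probes and 11 lists. Within the slide of arrays 2 to 4, fitted with a dye coefficient and so not of the same form, there were 285 probes and 7 lists. The split with 1054 probes turned array 2 as labelled but not array 4, which is neither reading of the dyes. As scanned, arrays 1, 3 and 4 correlated with each other across probes at r = 0.11 to 0.29. Array 2 correlated with arrays 1, 3 and 4 at r = -0.42, 0.02 and 0.07. A count over 3 times the real 323 can point to a structure of the samples, which was not tested.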
